A study of Mus with 6 samples.

How the data were processed

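RNA from flash-frozen liver tissue of wild type and Fabp4 knockout mice, 3 samples of each, was extracted with TRIzol, and libraries were sequenced on an Illumina HiSeq instrument, per the labels' protocols. FastQC and Trimmomatic were used and the genome build was mm10, per the submitters' processing notes; their versions, the aligner, the quantification tool and the annotation are not given in the sources used here, nor is strandedness. The deposited table is 1 matrix of genes by libraries. Its value columns are named TPM per the file headers, but the deposited values are on a log2 scale: they reach below 0, and their antilogarithms sum to 983800 to 1018120 per library. The sorted values of the 6 columns nearly coincide, with 1 shared maximum of 16.59 and minimum of -8.88 and medians of 1.07, which is what quantile normalization across libraries leaves. Neither the logarithm nor the normalization is named in the headers; both were read from the values. Under such a normalization the most abundant gene, Alb, has 1 and the same value in every library, so that it carries no information, and a shift of all genes between the groups cannot be seen. The deposited table also gives each gene's type, position, strand and length in bases, per the file headers.

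A blank value was taken as a TPM of 0, since a TPM of 0 has no logarithm. Of 48882 genes, 22222 had no value in any library, 9829 had a value in some and 16831 in all 6. Each of 20 housekeeping genes had a value in every library, and, Fabp4 left out, the highest TPM of a gene with a blank elsewhere was 16.1. The values were back-transformed to TPM, and the tests ran on log2(TPM + 1), a pseudocount of 1 that understates the change of low genes. Genes with a mean TPM of at least 0.5 over the 6 libraries were kept, 14155 in all. The design had been fixed for TPM values, and the back-transformation brought the deposited values to that unit. TPM keeps no depth, so the number of reads behind a value is unknown, count models were not used, and precision is set by the 3 libraries per group. All 6 value columns were used. The labels number the replicates of a group and speak of littermates, without stating that each number is a separate mouse. The p-values measure the spread between these libraries.

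The 2 groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, group as the only term, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Differences are knockout minus wild type. The fit had 4 residual and 3.65 prior degrees of freedom. The labels do not tie equal replicate numbers in the 2 groups to a shared litter, so the numbers were not a term of the model. The exact permutation test of 1 gene used every split of 3 against 3, for which the smallest p is 0.1. Before the data were examined, 29 gene lists with 505 different genes were fixed, covering fatty acid-binding proteins, ethanol oxidation, lipid, cholesterol, bile acid, drug and glucose metabolism, stress, inflammation, interferon, fibrosis, cell death, cell cycle, clock and sex-biased genes, and markers of hepatocytes and 8 other cell types. All 505 were matched to the table, 3 of them through an older symbol or gene number with the GRCm38.p6 RefSeq gene table. Lists with at least 3 members past the filter, 28 of the 29, were tested with camera of limma at a preset inter-gene correlation of 0.01 and, as an alternative, with the correlation estimated for each list, Benjamini-Hochberg adjusted over the lists. A member is said to pass over the list alone when its p, adjusted within the list, is under 0.05. A list score is the mean over members of log2(TPM + 1) minus the gene's mean over the libraries, and the SE of a list's mean difference comes from the scores of the 6 libraries.

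Genes named in the text were chosen by a rule fixed before the data were examined: Fabp4 and its family, the 10 genes higher and the 10 lower with no overlap between groups and a mean of at least 1 TPM in the higher group (those past the threshold first, then by smallest p), and in each list up to 4 members with the smallest p. Predicted genes, pseudogenes and unnamed clones, here also genes with only an Ensembl number and those of the type TEC, were counted but not named. Some genes that the rule names are not reported here. Other genes, including Xist and the Y-linked genes, Cd36, Cyp2e1, Aldh2, Hamp, Saa3, Ighm and the members past the list-alone threshold, were chosen after their values were seen. The table has 12 gene names turned into dates by a spreadsheet, which were left as they are. SE stands for standard error and SD for standard deviation.

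The tests were tested on simulated data drawn from the real genes' means and spread for the knockout against wild type comparison (14155 genes, 20 simulated sets). Of 200 genes changed in each set, limma recovered 71.9% of those changed by 1 on the log2 scale, 97.9% of those changed by 2 and 99.5% of those changed by 3, and 5.58% of the calls were false. A simulated list of 20 genes shifted by 0.8 was called in 20 of 20 sets, and 0 of 540 unshifted lists were called. The simulated genes varied independently, which real genes do not. Their spread was the moderated one of the limma fit, which differs less between genes than the raw spread. The 200 changed genes in each set also ease the adjusted threshold. The recovery can therefore overstate what these 6 libraries allow. The count of 0 unshifted lists called holds for independent genes only. In these data, other splits of the 6 libraries called 6 to 15 lists at the preset correlation. Alternatives covered the pseudocount, the filter, scaling, variance moderation, array weights (limma), the replicate number as a block, camera settings, the threshold, the window around Fabp4 and leaving out each library; 3 more were added after the data were seen.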

Results

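RNA was sequenced from 6 liver samples in 2 groups, 3 of mice lacking Fabp4 and 3 of their wild type littermates. The mice had received a Lieber-DeCarli diet, a liquid feed that carries ethanol, for 8 weeks and then 1 ethanol binge, a regimen used to produce alcoholic steatohepatitis (ASH, fatty liver disease with inflammation). Fabp4 encodes a fatty acid-binding protein best known from adipocytes, macrophages and capillary endothelium. The comparison asks which liver transcripts differ when Fabp4 is missing in mice with ASH, and livers without ethanol were not analysed here. Expression was given for 48882 genes in columns named TPM, a transcript's share of all transcripts corrected for its length. The values look quantile normalized across libraries, so they are no longer exact shares. Of the genes, 20664 to 21438 had a value in any 1 library, and 14155 passed the abundance filter and were tested. TPM keeps no sequencing depth, so the depth of the libraries is unknown and no counting interval can be given. No 2 libraries held identical values, and across genes the mean correlation of a library with the others lay between 0.974 and 0.980. Wild type replicate 2 lay apart from the rest on the first principal component (-38.1, against -2.50 to 22.3 for the other libraries; 33.9% of the variance), and knockout replicate 1 on the second (-30.8, against -5.92 to 21.8; 21.6%). Xist, which is transcribed from the inactive X chromosome, lay between 60.4 and 85.0 TPM in all 6 libraries, and the summed TPM of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty was at most 0.0704.

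Fabp4 itself (mm10 chromosome 3, 10204342 to 10208602, minus strand) was measured at 14.7, 8.15 and 19.96 TPM in wild type replicates 1, 2 and 3 and was listed without a value in each of the 3 knockout libraries. On the log2(TPM + 1) scale the difference was -3.85 (SE 0.28), with a Benjamini-Hochberg adjusted p of 0.0168 from limma. No fold is given, since 1 group has no value, taken as 0, and the log2 difference depends on the pseudocount. The exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. Of the other 9 intracellular fatty acid-binding protein genes, 4 were abundant enough to test and none passed. Fabp1, the liver form, averaged 5439 ± 1255 TPM (SD, n = 3) in wild type and 7384 ± 573 TPM (SD, n = 3) in the knockout, a log2 difference of 0.47 (SE 0.20). Fabp5, the form closest to Fabp4 in adipocytes and macrophages, averaged 78.1 ± 74.8 TPM (SD, n = 3) and 52.1 ± 27.4 TPM (SD, n = 3), a difference smaller than the spread between libraries (log2 -0.24, SE 0.74). The log2 differences of Fabp2 and Fabp7 were -0.05 (SE 0.22) and 0.46 (SE 0.34). As a list these 4 genes gave a limma camera adjusted p of 0.507.

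Fabp4 was the only gene past the threshold in the test over all genes (limma, Benjamini-Hochberg; 1 lower and 0 higher of 14155), and the next smallest adjusted p was 0.183. At an unadjusted p under 0.05 there were 1137 genes, 725 higher and 412 lower in the knockout, against 707.75 that chance alone gives. That split depended on scaling, with 507 higher and 586 lower after median scaling and 570 higher and 537 lower after quantile normalization. The 3 knockout values lay wholly above or below the 3 wild type values for 1886 genes (13.3%, where chance gives 10%). Fabp4 also lost its call when wild type replicate 1 (limma adjusted p 0.176), knockout replicate 1 (0.0922) or knockout replicate 2 (0.157) was left out, without a filter (0.145) and with the replicate number as a block (0.0820). Its log2 difference stayed between -4.18 and -3.58 in the fits that left out a library.

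The genes with the smallest p-values and no overlap between groups were, besides Fabp4, 19 genes that did not pass the threshold. Higher in every knockout library were Ppp1r3c, a glycogen-targeting subunit of protein phosphatase 1, at 29.5 ± 5.52 TPM (SD, n = 3) against 10.5 ± 1.23 TPM (SD, n = 3; log2 1.40, SE 0.17), and Angptl8, a feeding-induced secreted regulator of lipoprotein lipase, at 217 ± 84.4 TPM (SD, n = 3) against 40.3 ± 22.5 TPM (SD, n = 3; log2 2.46, SE 0.45). Fam198a (log2 1.13, SE 0.16), the matrix proteoglycan gene Lum (0.77, SE 0.12), the interferon-inducible Ifi27 (0.63, SE 0.10), the microtubule regulator Stmn1 (0.86, SE 0.15), the immunoglobulin D heavy chain gene Ighd (1.02, SE 0.18), Igsf8 (0.71, SE 0.13) and the small nucleolar RNA Snora20 (1.05, SE 0.17) were also higher in all 3. The tRNA gene n-TWcca7 had no value in wild type, which was taken as 0, and was at 1.14 to 1.46 TPM in the knockout, low values of a short gene. Lower in every knockout library were the NKG2D ligand gene Raet1d (log2 -1.18, SE 0.15), the glycerophosphocholine phosphodiesterase Gpcpd1 (-1.08, SE 0.16), the hepatic transcription factor Onecut1 (-1.16, SE 0.21), the corepressor Tle3 (-0.74, SE 0.14) and Fbxo31 (-0.83, SE 0.16), besides 4 acute-phase genes, Orm2, Orm3, Saa1 and Saa2. The limma adjusted p of these 19 genes lay between 0.183 and 0.522.

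**Figure D1:**
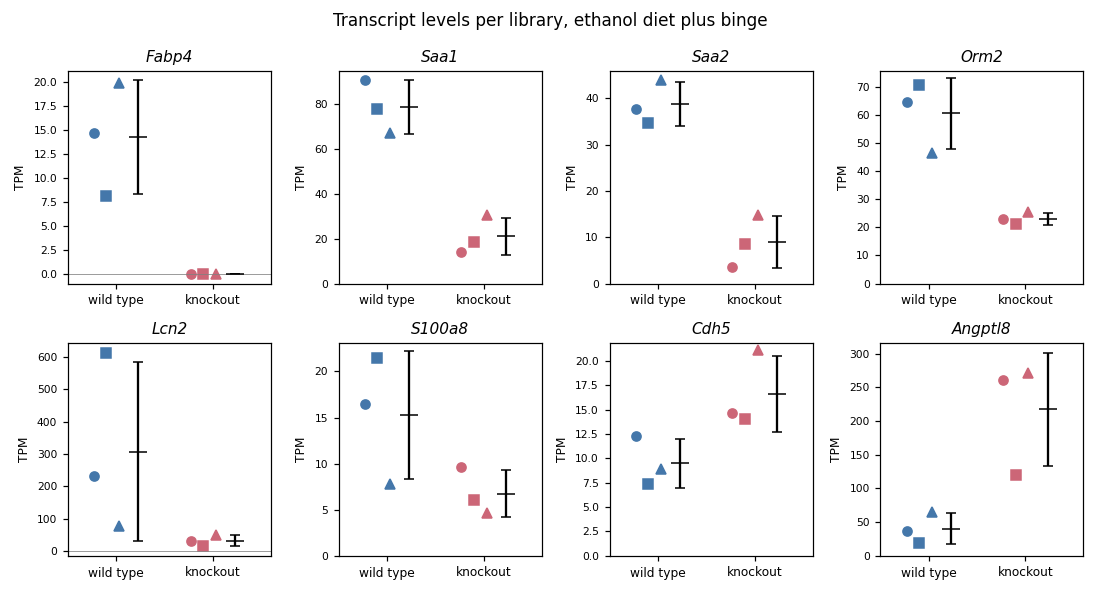
TPM of 8 genes in each library (points, 1 marker shape per replicate number) with the group mean and SD (black bars), for wild type and Fabp4 knockout. Fabp4, without a value in the knockout libraries, is drawn at 0 there. Saa1, Saa2, Orm2 and Lcn2 lie lower and Cdh5 and Angptl8 higher in each knockout library, while the S100a8 values overlap.

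Of 28 gene lists fixed in advance, 10 passed the limma camera threshold at the preset correlation, 6 higher and 4 lower, and 0 passed with an estimated correlation. The list with the smallest p was the acute-phase response, genes that hepatocytes switch on in inflammation, and it was lower in the knockout libraries. Of the 24 measured members, 22 were lower, and 15 passed when adjusted over the list alone (limma, Benjamini-Hochberg), all of them lower, against 0 over all genes tested. Saa1 (mm10 chromosome 7, 46740497 to 46743071), a serum amyloid A gene, averaged 78.7 ± 11.9 TPM (SD, n = 3) in wild type and 21.0 ± 8.41 TPM (SD, n = 3) in the knockout. Saa2 (chromosome 7, 46751769 to 46754314) averaged 38.8 ± 4.72 and 9.01 ± 5.60 TPM (SD, n = 3 each). The orosomucoid gene Orm2 averaged 60.4 ± 12.6 and 23.0 ± 2.11 TPM (SD, n = 3 each). Lcn2, which encodes the siderophore-binding lipocalin 2, was at 232, 614 and 76.1 TPM in the wild type libraries and at 31.8, 14.98 and 49.7 TPM in the knockout libraries. The fibrinogen genes Fga (log2 -1.04, SE 0.38) and Fgg (-0.96, SE 0.34), Apcs, Steap4, Orm1, Orm3, Serpina3m, Serpina3n, Cebpd, Lbp and Saa4 completed the 15. The 2 members that were not lower were Hamp (0.50, SE 0.62), the iron hormone hepcidin, and Saa3 (0.07, SE 0.44). The mean log2 difference of the list was -0.87 (SE 0.21), and the limma camera adjusted p was 1.95e-19 with the preset correlation. The limma camera adjusted p = 0.318 with an estimated correlation between genes (unadjusted p 0.0114), so the list call rests on the preset. Wild type replicate 2, which lay apart on the first principal component, had the highest acute-phase score of the 6 libraries (0.79), and without it the mean difference was -0.70. The near-identical copies Saa1 and Saa2, and Orm1, Orm2 and Orm3, can share reads, and their separate values are uncertain. The number past the list-alone threshold ranged from 5 without knockout replicate 2 to 21 without wild type replicate 3. It was 7 without wild type replicate 1, 8 without wild type replicate 2, 9 without knockout replicate 1 and 6 without knockout replicate 3.

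**Figure D2:**
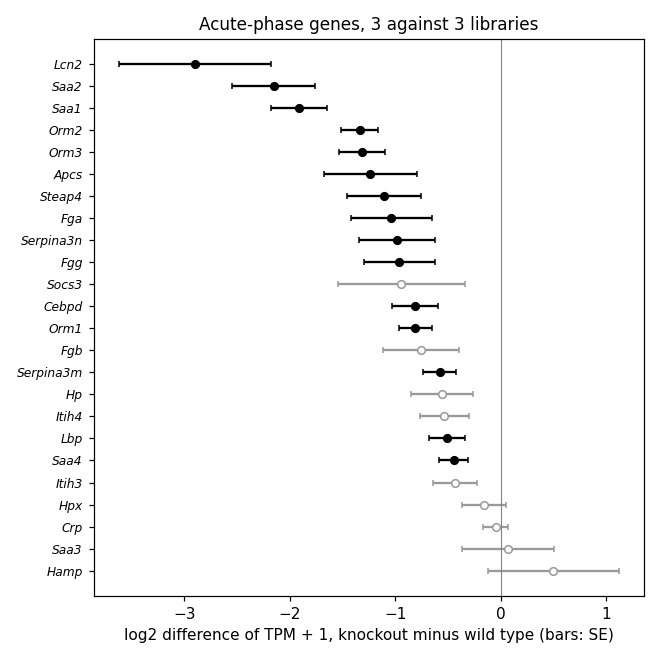
Log2 difference of TPM + 1, knockout minus wild type, for the 24 acute-phase genes (points) with its SE from limma (bars). Filled points passed at an adjusted p under 0.05 over the list alone, 15 of the 24, all lower in the knockout.

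Other inflammatory genes did not move as 1 group. The 4 measured neutrophil markers were all lower, and S100a8 (log2 -1.02, SE 0.36), S100a9 (-0.73, SE 0.25) and Retnlg (0.656 ± 0.0799 TPM against 2.61 ± 1.61 TPM in wild type, SD, n = 3 each) passed when adjusted over the list alone, against 0 over all genes. The list's limma camera adjusted p was 0.00155, and the adjusted p = 0.692 with an estimated correlation. The call was also lost without knockout replicate 1 (0.0502), and wild type replicate 2 had the highest neutrophil score (0.71). Over the list alone 3 members passed without wild type replicate 3, and 0 without any 1 of the other 5 libraries. The other 9 of the 13 neutrophil markers, among them Ly6g, Mpo and Elane, fell under the abundance filter. Cytokines, chemokines and NF-kB targets were split evenly, 10 higher and 10 lower, with no member past the list-alone threshold and a limma camera adjusted p of 0.401. The mean and the test pointed down and the median up. Without wild type replicate 1 the list passed higher (adjusted p 0.0415 from limma camera), with 1 member past the list-alone threshold, and without wild type replicate 2 it passed lower (0.00227). Cxcl1, a neutrophil-attracting chemokine, was at 31.6, 119 and 8.35 TPM in wild type and at 13.6, 4.73 and 10.5 TPM in the knockout. Interferon-stimulated genes were higher for 20 of 24 members (mean log2 0.23, SE 0.22), with Ifi27 and Bst2 past the list-alone threshold (limma camera adjusted p 0.00883; adjusted p = 0.848 with an estimated correlation). That call was lost without wild type replicate 2 (0.502, mean 0.07), knockout replicate 2 (0.172) or knockout replicate 3 (0.0846). The number past the list-alone threshold was 0 without knockout replicate 2, 3 without wild type replicate 1 (mean 0.39) and 1 without any other library or after each further scaling. Ifi27 averaged 73.0 ± 0.614 TPM (SD, n = 3) in wild type and 114 ± 0.785 TPM (SD, n = 3) in the knockout.

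Markers of several cell types other than hepatocytes were higher in the knockout. Endothelial markers were higher for 14 of 15 members (mean log2 0.40, SE 0.12), and 8 passed when adjusted over the list alone, against 0 over all genes. They were Ehd3, Fcgr2b, Oit3, Kdr, Cdh5, Pecam1, Tek and Gpr182. Ehd3, an endocytic gene of sinusoidal endothelium, averaged 29.8 ± 6.16 TPM (SD, n = 3) in wild type and 51.8 ± 4.98 TPM (SD, n = 3) in the knockout. The VEGF receptor Kdr averaged 13.8 ± 0.722 and 19.2 ± 2.10 TPM (SD, n = 3 each). The limma camera adjusted p was 2.26e-07, and the adjusted p = 0.692 with an estimated correlation. None of the 15 passed the list-alone threshold without wild type replicate 2, wild type replicate 3 or knockout replicate 3, and 5 did without knockout replicate 1 or after median scaling. Macrophage and monocyte markers were higher for 20 of 21 members (mean log2 0.63, SE 0.42), none past the list-alone threshold (9 without wild type replicate 1 and 3 without knockout replicate 1). They had a limma camera adjusted p of 8.60e-06 and an adjusted p = 0.692 with an estimated correlation. The Kupffer cell genes Vsig4 and Timd4 were highest in knockout replicate 3, at 109 and 17.2 TPM, against 27.5 to 40.7 and 3.36 to 4.35 TPM in wild type. The list's mean was 0.36 without knockout replicate 3 and 0.41 without wild type replicate 2. The list score of wild type replicate 1 (0.29) lay above those of knockout replicates 1 (-0.01) and 2 (0.08). Fibrosis and stellate cell genes were higher for 19 of 22 members (mean log2 0.21, SE 0.11), with Lum past the list-alone threshold at 7.52 ± 0.0824 TPM (SD, n = 3) in wild type and 13.5 ± 1.11 TPM (SD, n = 3) in the knockout. Their limma camera adjusted p was 0.00677 (adjusted p = 0.692 with an estimated correlation), and the call was lost without wild type replicate 2 (0.0868, mean 0.13) and without knockout replicate 1 (0.144). Beside these lists stands the position of wild type replicate 2, which had the lowest endothelial (-0.37), macrophage (-0.75) and fibrosis (-0.28) scores of the 6 libraries. Without that library and knockout replicate 1, a setting added after the data were seen, the limma camera adjusted p was 0.000471 for the endothelial and for the macrophage list and 0.539 for the fibrosis list.

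Lymphocyte markers were higher for 8 of 10 members (mean log2 0.43, SE 0.25), and the B cell genes Cd79b and Ms4a1 passed over the list alone. Cd79b averaged 0.796 ± 0.491 TPM (SD, n = 3) in wild type and 2.42 ± 0.327 TPM (SD, n = 3) in the knockout. The limma camera adjusted p was 0.0482 (adjusted p = 0.711 with an estimated correlation), and the call was lost in 9 further settings, among them without knockout replicate 1 (0.216, mean 0.21), wild type replicate 2 (0.108) or wild type replicate 3 (0.225). No member passed over the list alone without wild type replicate 2, wild type replicate 3 or knockout replicate 3. Without wild type replicate 1 there was 1, and without knockout replicate 2 there were 3. Knockout replicate 1 carried more immunoglobulin RNA than the others, with Ighm at 74.2 TPM against 4.17 to 11.1 TPM. Cell cycle genes were higher for all 16 measured members (15 after median scaling or quantile normalization), with a mean log2 difference of 0.59 (SE 0.30) and none past the list-alone threshold (1 without knockout replicate 2). Without knockout replicate 3 the mean was 0.33, with 13 of 14 measured members higher. Their limma camera adjusted p was 6.67e-05, and the adjusted p = 0.692 with an estimated correlation. The replication licensing genes were highest in knockout replicate 3, where Mcm3 and Mcm5 were at 15.8 and 13.0 TPM, against 0.831 to 5.18 TPM in the other libraries. Hepatocyte genes were not different as a list (7 higher and 10 lower, mean log2 -0.05, SE 0.11, limma camera adjusted p 0.401). The 10 include Alb, which is equal in all libraries and counted as lower only through rounding. Cholangiocyte markers (0.310), red blood cell transcripts (0.296) and the 4 measured adipocyte markers (0.693; mean and median up, test down) were not different either. Hepatocyte genes passed, lower, without wild type replicate 2 (limma camera adjusted p 0.0126). Cholangiocyte markers passed, higher, without wild type replicate 2 (0.00939) or knockout replicate 3 (0.00619), and red blood cell transcripts passed, higher, without knockout replicate 1 (0.00312). Exocrine pancreas markers had 1 member past the filter, Cela1, and the list was not tested.

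**Figure D3:**
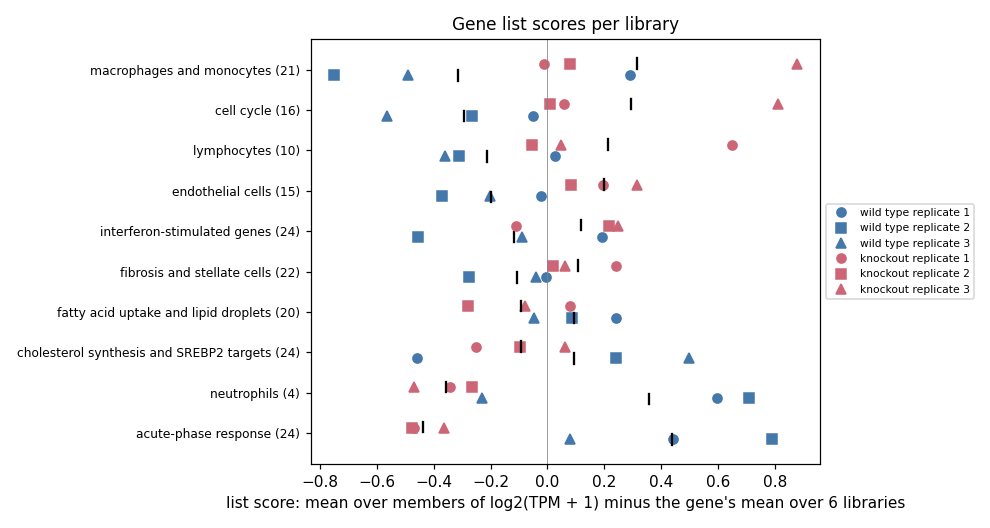
List scores in each library for the 10 gene lists with a limma camera adjusted p under 0.05 at the preset correlation (members measured in parentheses), as the mean over members of log2(TPM + 1) minus the gene's mean over the 6 libraries. Points are libraries and black ticks group means; acute-phase scores lie between 0.08 and 0.79 in wild type and between -0.48 and -0.36 in the knockout, while the macrophage scores overlap.

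Lipid genes were compared because Fabp4 carries fatty acids and ASH begins with fat storage. Genes of fatty acid uptake and lipid droplets were lower for 13 of 20 members (mean log2 -0.19, SE 0.13), none past the list-alone threshold (1 without wild type replicate 3). The lipid droplet coat gene Plin2 averaged 742 ± 185 TPM (SD, n = 3) in wild type and 457 ± 49.3 TPM (SD, n = 3) in the knockout. The triglyceride lipase gene Pnpla2 averaged 52.5 ± 11.7 and 37.8 ± 1.31 TPM (SD, n = 3 each). Plin4 (log2 -0.75, SE 0.29) and Lipe (-0.33, SE 0.14) had the next smallest p-values, and Cd36 was close to equal in the 2 groups (-0.04, SE 0.16). The list's limma camera adjusted p was 0.00883 (adjusted p = 0.692 with an estimated correlation). The call was lost without a filter (0.0605), with a filter at 5 TPM (0.0983) and without knockout replicate 2 (0.0868, mean -0.09), and the mean was -0.11 without wild type replicate 1. Cholesterol synthesis genes were lower for 16 of 24 members (mean log2 -0.19, SE 0.30; 0 past the list-alone threshold), with Sqle at 18.1 ± 12.3 TPM (SD, n = 3) and 5.79 ± 1.42 TPM (SD, n = 3) and Hsd17b7 at log2 -0.54 (SE 0.18). Their limma camera adjusted p was 0.00722 (adjusted p = 0.848 with an estimated correlation). It became 0.901 without wild type replicate 3, where the mean difference was 0.01, 0.242 without knockout replicate 1 and 0.132 with array weights. Without wild type replicate 1 it was 1.19e-11, with 21 of 24 members lower, 6 of them past the list-alone threshold, and a mean of -0.46. The mean was -0.11 without wild type replicate 2, where the list still passed (0.0437). Lipogenesis genes gave no list call (14 of 20 higher, mean log2 0.27, SE 0.32, limma camera adjusted p 0.507), but passed, higher, without wild type replicate 3 (1.24e-05), with 3 members past the list-alone threshold. Fasn was at 28.2, 26.6 and 137 TPM in wild type and at 67.4, 110 and 150 TPM in the knockout, and Acacb averaged 16.9 ± 3.47 and 10.5 ± 1.99 TPM (SD, n = 3 each). Fatty acid oxidation genes and PPARa targets gave no call (15 of 27 lower, limma camera adjusted p 0.235). Cpt1a (log2 -0.58, SE 0.18) and Ppara (-0.68, SE 0.22) were lower, neither past the list-alone threshold. The list passed, lower, without wild type replicate 2 (0.0125), wild type replicate 3 (0.00725, with 4 members past the list-alone threshold, lower) or knockout replicate 2 (0.0311), and its mean ranged from -0.26 to 0.10 when 1 library was left out.

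The remaining lists gave no call with all 6 libraries under the main settings. Of the genes that oxidise ethanol and acetaldehyde, 10 of 14 were higher (8 after median scaling; limma camera adjusted p 0.455). Adh1, the main hepatic alcohol dehydrogenase, averaged 2277 ± 345 TPM (SD, n = 3) in wild type and 3732 ± 676 TPM (SD, n = 3) in the knockout. The log2 differences of Cyp2e1 and Aldh2 were -0.10 (SE 0.20) and 0.08 (SE 0.13). In the oxidative stress list (limma camera adjusted p 0.796, 0.0266 without knockout replicate 2; mean and test down, median up) the metallothionein genes Mt1 and Mt2 passed over the list alone, with 343, 1884 and 383 TPM for Mt1 in wild type and 181, 33.6 and 49.7 TPM in the knockout. Neither passed over all genes, and both lost the list-alone call without a filter and without wild type replicate 3, knockout replicate 2 or knockout replicate 3. Without wild type replicate 2, 1 member was past it, lower. In the unfolded protein and integrated stress list 16 of 21 members were higher (limma camera adjusted p 0.0768). That list passed, higher, after median scaling (0.0304), after quantile normalization (0.0260), with camera on ranks (0.0255), without wild type replicate 2 (0.00648) and without knockout replicate 2 (4.89e-05). The chaperone gene Hsp90b1 was higher (log2 0.73, SE 0.26) and the amino acid response gene Asns lower (-1.64, SE 0.37), neither past the list-alone threshold. Asns came close (limma p adjusted over the list 0.0522). With both other pseudocounts, the filter at 5 TPM and all 3 scalings, 1 member passed over the list alone, lower. Without knockout replicate 2 the list's mean was 0.50, against 0.28 with all libraries, and 8 members passed over the list alone higher and 1 lower. The glucose metabolism list (limma camera adjusted p 0.507; mean and test down, median up) held Igfbp1, a fasting-induced secreted protein, at 294 ± 11.99 TPM (SD, n = 3) in wild type and 76.0 ± 50.1 TPM (SD, n = 3) in the knockout, and Irs2 (log2 -1.10, SE 0.34). In the drug metabolism list (limma camera adjusted p 0.289, 0.00360 without knockout replicate 2; mean and test down, median up) Sult1e1 (log2 -2.39, SE 0.61) and Cyp2b10 (-0.87, SE 0.24) had the smallest p-values. Bile acid genes (0.827; mean and median up, test down), cell death genes (0.827; mean and median up, test down), clock genes (0.796; mean up, median and test down), and male-biased (0.289) and female-biased (0.289) liver genes gave no call either, the values in parentheses being limma camera adjusted p. Abcb11 (log2 0.65, SE 0.27), Usp2 (0.41, SE 0.28), Cyp2d9 (-0.74, SE 0.26) and Sult3a1 (-1.63, SE 0.44) were among their members with the smallest p-values.

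Genes near Fabp4 were tested because a knockout allele can carry flanking sequence of another strain. Of the 35 tested genes within 10 Mb of Fabp4, 0 passed the limma threshold, and 1 (2.86%) had an unadjusted p under 0.05, against 8.04% of the genes elsewhere (Fisher's exact test, two-sided, p = 0.525). With 0 other genes called, the count of calls could not differ between the 2 places.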

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

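The comparison with the hepatocyte list, the mean of members without near-identical copies, the endothelial minus neutrophil score, the list means without 1 library and the splits of the acute-phase and endothelial lists were tests chosen after the results they bear on had been seen. The other tests here were set down before their values were known.

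Adipoq, the adipocyte hormone adiponectin, lay under the abundance filter, which kept it out of the filtered gene and list tests. It entered the fit without a filter and the gene length test of knockout replicate 1. It was measured at 1.99 TPM in knockout replicate 1 and had no value in any of the other 5 libraries, wild type or knockout, a signal of 1 library among the genes that the filter leaves out.

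Acute-phase genes were lower in the knockout libraries. Fewer hepatocytes would lower other hepatocyte genes alike. The mean log2 difference of 15 hepatocyte genes (without Alb and the shared Fgb) was -0.0062 (SE 0.15) against -0.87. The acute-phase genes thus fell relative to other hepatocyte genes. Whether the share of hepatocytes itself fell cannot be decided, since quantile normalization would hide a joint fall of the most abundant genes. The hepatocyte list also passed, lower, without wild type replicate 2 (limma camera adjusted p 0.0126). Reads shared between copies cannot account for the 15 members that are no Saa, Orm or Serpina3 gene, whose mean was -0.77 (SE 0.31). Shared reads leave the separate values of the copies uncertain. Without any 1 library the list's mean stayed between -1.05 and -0.70, which argues against 1 library as the whole cause. It lay beyond 2 SE of 0 each time, closest without wild type replicate 1 at -0.87 (SE 0.36). Such an SE rests on 2 libraries in 1 group, so 2 SE is a loose bar. The list's median lay at percentile 0 of 10000 random lists matched on mean expression, which argues against an abundance-dependent shift. A weaker acute-phase response without Fabp4 is a candidate explanation, a hypothesis found and tested on the same 6 libraries and at the preset correlation only, while litter, cage and the stress or feeding state at collection stay open.

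Endothelial and macrophage markers were higher in the knockout and neutrophil markers lower. A lower share of hepatocytes would raise all other cell types alike. The endothelial score rose above that of the 4 measured neutrophil markers by 1.11 (SE 0.34). That difference restates the opposite directions already seen, so it cannot decide the question for the lists that rose. The mean log2 difference was also above 0 for the lymphocyte (0.43), cholangiocyte (0.23), red blood cell (0.22), fibrosis and stellate cell (0.21) and adipocyte (0.19) lists. A lower share of hepatocytes stays open for the lists that rose, and would not by itself lower neutrophil markers. Without any 1 library the endothelial mean stayed between 0.31 and 0.48. It lay beyond 2 SE of 0 each time, closest without wild type replicate 3 at 0.39 (SE 0.19). Such an SE rests on 2 libraries in 1 group, so 2 SE is a loose bar. The macrophage mean of 0.63 (SE 0.42) lay within 2 SE of 0 with all libraries. It was 0.41 (SE 0.48) without wild type replicate 2, so the part of single libraries in the macrophage mean stays open. A change in the number or state of endothelial cells and macrophages may underlie the pattern, as may a difference in where the liver piece was taken, and neither was tested. Neither list passed with an estimated correlation.

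Fat and B cell transcripts stood out in knockout replicate 1, where Cfd was at 5.94 TPM against at most 0.105 elsewhere, 6 of 8 fat markers had a value against 1 or 2 in the other libraries, and Igkc was at 169 TPM against 25.3 to 46.5. That library also favoured short genes (Spearman correlation of its deviations with gene length -0.307, across genes, which are not independent), but the 10 fat and B cell genes kept a median log2 excess of 0.573 over genes of like length and level, against 0.565 before, which argues against a length trend. Adipose tissue in the liver piece may be a source of the fat transcripts. Of 14 further fat genes with a value 5 were highest in this library, against 1 in 6 by chance (one-sided exact binomial p = 0.0690), which leaves it undecided. Among the 14, Adipor2 (187 to 248 TPM) and Gpd1 (223 to 347 TPM) were abundant in every library. A trace of fat could hardly make these 2 highest, which weakens the test. Fabp4 cannot mark fat in a knockout, and a source of the B cell transcripts was not tested. No biological explanation was tested, since the pattern is in 1 library.

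The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1 gene past the limma threshold and the highest of the others 0, so that 1 of the 10 splits reached the real count. That 1 gene was Fabp4, the deleted gene itself, which favours the real split in advance, so this count decides nothing. Besides Fabp4 the real split called 0 genes, as did the others. At an unadjusted p under 0.05 the real split gave 1137 genes and the highest other 1549, with wild type replicate 1 and knockout replicates 2 and 3 on 1 side, and 2 of the 10 splits gave at least 1137. For gene lists at the preset correlation the real split gave 10 calls, the highest other 15 and the lowest other 6. At least 10 were given by 5 of the 10 splits. Every other split thus called lists at the preset. The acute-phase list had a limma camera adjusted p under 0.05 in 5 of the 9 other splits, the smallest 2.84e-07 against 1.95e-19 for the real split, and the size of its mean difference reached 0.58 in them against 0.87. The endothelial list did so in 5 of the 9 as well, the smallest 8.31e-06 against 2.26e-07, and the size of its mean reached 0.33 against 0.40.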

How the results depend on the processing

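Protein-coding genes alone, the deposited log2 values without back-transformation, and leaving out both wild type replicate 2 and knockout replicate 1 were tests chosen after the data were seen. Fabp4 was the 1 gene called by limma with both other pseudocounts, the filter at 5 TPM, all 3 scalings, both other variance moderations, array weights, protein-coding genes alone, an adjusted p under 0.1, and an added log2 difference of 1. Without a filter its log2 difference was -3.85 (limma adjusted p 0.145), and 0 genes were called of 26660 tested, with 1571 at an unadjusted p under 0.05. With the replicate block it was -3.85 (limma adjusted p 0.0820), with 0 genes called, 816 at an unadjusted p under 0.05 and 10 lists past the threshold. No pairing by number was seen: the correlations of same-numbered deviations were -0.261, -0.266 and -0.0494, and no library correlated best with its own number. So few correlations cannot exclude a shared litter. With the deposited log2 values limma called 0 genes, with 1312 at an unadjusted p under 0.05, and Fabp4, which has no value in the knockout, could not be tested. Without wild type replicate 2 and knockout replicate 1, 3 genes were called, Fabp4, Mt1 and a predicted gene. An unadjusted p under 0.05 with a log2 difference of at least 1 gave 104 genes, 43 higher and 61 lower, a weaker threshold by construction. With 1 library left out the count ranged from 0 to 6 and the log2 difference of Fabp4 from -4.18 to -3.58. The count was 0 without wild type replicate 1 (1215 at an unadjusted p under 0.05) or knockout replicate 2 (952), and 6 without wild type replicate 3 (Fabp4, Mid1ip1 and Orm2 among them). It was 4 without knockout replicate 3 (Fabp4, Saa1, Rn7s1 and Rn7s2), and the 1 gene called without knockout replicate 1 was a predicted gene. With an estimated correlation 0 lists passed limma camera, 1 at an unadjusted p under 0.05, against 10 with the preset of 0.01. The estimates for those 10 lay between 0.0814 and 0.645, and a higher correlation widens the error of the test by construction. In the other settings 7 to 12 lists passed, and the acute-phase, endothelial, macrophage and cell cycle lists did so in each setting at the preset correlation, although with 1 library left out the mean ranged from 0.36 to 0.93 for macrophages and from 0.33 to 0.78 for the cell cycle. The cytokine list's mean ranged from -0.31 to 0.22 with 1 library left out, and it turned direction without wild type replicate 1 (limma camera adjusted p 0.0415). Beyond fewer libraries and more genes tested, the cause was not tested. Median scaling moved the median of all genes by -0.05. Near Fabp4 limma called 0 genes with windows of 5 and 20 Mb too, where 1 of 24 and 5 of 45 genes had an unadjusted p under 0.05. The depth behind the values is unknown, so what it limits was not assessed. Counts were not used here, so the count models set down as alternatives were not run.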

Other observations

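The test of further fasting and glucocorticoid-induced genes was set down before its values were known, and the other values here were picked after they were seen.

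The 7SL RNA genes Rn7s1 and Rn7s2, which encode the RNA of the signal recognition particle, were at 702 and 2252 TPM in knockout replicate 1 and at 615 and 1878 TPM in knockout replicate 2. In the other 4 libraries, knockout replicate 3 included, they were at most at 19.3 and 42.5 TPM. Near-identical copies can share reads, so the separate values are uncertain. Exocrine pancreas transcripts were seen in 2 wild type libraries: of 10 markers (Cela1 left out) 8 had a value in wild type replicate 2 and 6 in wild type replicate 3, against 0 or 1 in the other libraries. Ctrb1, a chymotrypsinogen gene, was at 1.67 and 0.783 TPM in those 2 libraries and had no value in the others. The summed TPM of 42 immunoglobulin variable segments was 114 in knockout replicate 1, where 30 of them were highest, and 18.5 to 33.4 elsewhere. The mean TPM of the replication genes Mcm2 to Mcm6 was 15.2 in knockout replicate 3 and at most 4.66 in the other libraries.

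Igfbp1, Irs2, Asns, Mt1, Mt2 and Sult1e1 had lower means in the knockout, and Angptl8, which feeding induces, a higher one, none of them past the limma threshold over all genes with the 6 libraries. As a hypothesis, the 2 groups may have differed in feeding or stress state at collection. Of 15 further genes induced by fasting or glucocorticoids, 11 were lower and 4 higher, with a mean log2 difference of -0.26 (SE 0.0805), the direction that the hypothesis needs. Klf9 (log2 -0.65), Insig2 (-0.55), Gpt2 (-0.55), Fkbp5 (-0.45) and Cpt1b (-0.60) had an unadjusted p under 0.05, while the log2 difference of the glucocorticoid-induced Tsc22d3 was 0.58. Among other such genes in the lists fixed in advance, Pdk4 was at -1.58 and Cpt1a at -0.58, while Pck1 was at 0.19, G6pc at 0.17, Tat at 0.15 and Ppargc1a at 0.06, none past the list-alone threshold, so these genes did not all go 1 way. The test does not separate a difference at collection from an effect of Fabp4 loss on the same genes.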
